A study of Homo sapiens with 9 samples.

How the data were processed

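The series holds RNA sequencing of human CD4+ T cells in 9 libraries, 3 for each of 3 condition names. Per the labels' protocols, naive CD4+ T cells were cultured for 6 days either with activating anti-CD3 and anti-CD28 beads alone (named Th0) or with allogeneic plasmacytoid dendritic cells (pDC, the blood cells that make most type I interferon) at 6 T cells per pDC. The pDCs had been activated with CpG-A, a synthetic DNA ligand of TLR9, or with oxidised mitochondrial DNA, and these groups are called CpGA-pDC and Ox mtDNA-pDC. Cells with a diluted CFSE dye, meaning those that had divided, were sorted, and poly-A libraries were made from their total RNA. The labels number the libraries I, II and III in each group and call them biological replicates, but do not say what a number stands for.

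The deposited table holds whole-number read counts per gene, with no normalisation by the authors that the file shows. Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt, aligned with HISAT2 to GRCh38, handled with SAMtools and counted with HTSeq. Versions, parameters, the annotation release and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and genes that share reads with a near-identical copy are reported as uncertain.

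The table had 66206 gene identifiers, of which 57055 matched GENCODE 29 once the version was removed and 52238 matched with it. Coordinates are from GENCODE 29 on GRCh38, counted from 1. The identifiers without a match, which could lie on alternate loci or in another release, held between 0.175% and 0.321% of a library's counts. They stayed in the tests and library sizes, and no value of a single one is given. X-inactivation and Y-linked genes, 567 identifiers in all, were removed before any test, and single values of HLA genes and of antigen receptor segments are not reported. Total counts per library before this removal lay between 11178547 and 15580231, and a range of this kind limits precision mainly for genes under about 1 CPM, the read count of a gene scaled to a common library total.

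Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test, TMM scaling, the filterByExpr filter at its default minimum count of 10 and Benjamini-Hochberg adjustment, in a single fit of all 9 libraries with the group as the only term. This left 15084 genes. Every adjusted p of a single gene is from this test unless another is named, with a threshold of 0.05, and log2 fold changes are given with their standard error (SE). The SE of a gene was taken as the size of its log2 fold change over the square root of its F value. Levels are TMM-scaled CPM as mean ± SD of 3 libraries. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings and filters, the 2 compared groups alone, a minimum log2 fold change of 1, an adjusted p under 0.01, each library left out in turn, and the replicate number as a block. These designs, the 32 gene lists and the rule for named genes were fixed before the data were examined.

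Whether the numbers pair the libraries was checked on log2 CPM, as the correlation of each library's deviation from its group mean with that of libraries in the other groups. All 9 pairs with the same number correlated, at 0.718 to 0.877, against -0.702 to 0.272 for pairs with different numbers, and each of the 9 libraries correlated best with its own number. The pairing comes from the data alone, since the labels do not state it. The block lowered edgeR's common biological coefficient of variation from 0.403 to 0.0968, and values with the block stand beside each result whose call or count it changed.

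Gene lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 96 tests (32 lists in 3 comparisons), and again with an estimated correlation, with the block and with fry. The lists covered cytokines and helper T cell programs, cytotoxic and inhibitory molecules, receptors, interferon response, cell cycle, metabolism, mitochondrial and stress genes, and markers of cell types that a sort could carry along. All of their members were found in the table. The key gene list (IL10, IFNG, IL21, IL3, IL2, IL4, CXCR3, CXCR5, PDCD1, CD40LG, FOXP3, BCL6, PRDM1, SDHA, SUCNR1 and GPD2) was chosen from the series title and knowledge of the study, so a count over it is not independent evidence.

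Genes were named by this rule: for each comparison, up to 5 genes with the largest rise and 5 with the largest fall among those past the threshold with a mean of at least 5 CPM and no overlap between the groups; the key genes; the members with the smallest adjusted p of each described list (3, or 4 of a list with more than 20 tested members); and the members of the mtDNA-encoded and Complex II lists. All of these were chosen from the fit without the block. X-inactivation, Y-linked, receptor segment and unnamed genes were excluded, as were HLA genes. Comparisons between replicate numbers, with the group as a block, were added after the data were seen and use the same rule.

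Libraries were compared for duplicates by the chi-square per gene of their scaled counts, where sampling noise alone gives about 1. It was at least 3.1 in all 36 pairs, so none was counted as a repeat. The scripts were tested on simulated counts for 15084 genes with replicate number effects and 200 changed genes. In the simulated comparison of Ox mtDNA-pDC with Th0, the fit without the block recovered 9% of 2-fold and 55% of 4-fold changes with 0 unchanged genes called, and the block recovered 72% and 96% with 19 unchanged genes among 187 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Intervals are not given for shares, since reads without molecular identifiers are not independent molecules.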

Results

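Gene expression was measured in 9 poly-A RNA libraries of human CD4+ T cells that had divided during 6 days of culture. There were 3 libraries from cells cultured with activating beads alone (Th0), 3 from cells cultured with CpG-A-activated plasmacytoid dendritic cells (CpGA-pDC) and 3 from cells cultured with pDCs activated by oxidised mitochondrial DNA (Ox mtDNA-pDC). Total counts were 13867396, 15580231 and 15254314 in the Th0 libraries I, II and III. They were 11178547, 13026894 and 11372927 in the CpGA-pDC libraries and 14081888, 14763672 and 13481402 in the Ox mtDNA-pDC libraries. The series title names a CD4+ T cell population in lupus blood that helps B cells through IL10 and succinate, and the comparisons ask how T cells after each pDC co-culture differ from bead-activated cells and from each other.

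The cytokine genes IL10 and IFNG varied more between libraries with different replicate numbers than between the 3 condition names. IL10, which encodes an immune-regulatory cytokine (chromosome 1, 206767602 to 206772494, GRCh38), stood at 38.8, 214 and 0.0636 CPM in the Th0 libraries I, II and III. It stood at 93.7, 311 and 0.0863 CPM in the CpGA-pDC libraries and at 29, 173 and 1 CPM in the Ox mtDNA-pDC libraries. IFNG, which encodes interferon gamma (chromosome 12, 68154768 to 68159747), had 30.5, 168 and 0.318 CPM in Th0, 48.9, 270 and 0.691 CPM in CpGA-pDC and 37.1, 132 and 17.7 CPM in Ox mtDNA-pDC. Over all 15084 genes tested, the median share of a gene's variance that followed the replicate number was 76.4%, and the median share that followed the condition name was 9.3%. These shares are not corrected for chance. A grouping without any effect also takes up some variance, so the 9.3% alone does not show an effect of the condition. The first principal component held 52.5% of the variance and set the 3 libraries numbered III apart from the other 6. The libraries are therefore called by their labels throughout, as the libraries labelled Th0, CpGA-pDC and Ox mtDNA-pDC.

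**Figure D1:**
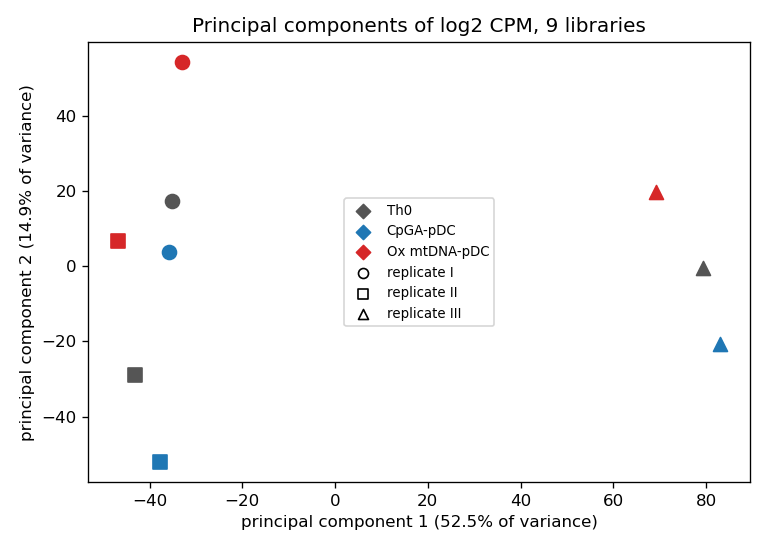
Principal components of log2 CPM over 15084 genes, each axis in units of component score with its percent of variance. Each point is 1 library, with the colour giving the condition name and the shape the replicate number; the first component, with 52.5% of the variance, sets replicate III of all 3 conditions apart.

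**Figure D2:**
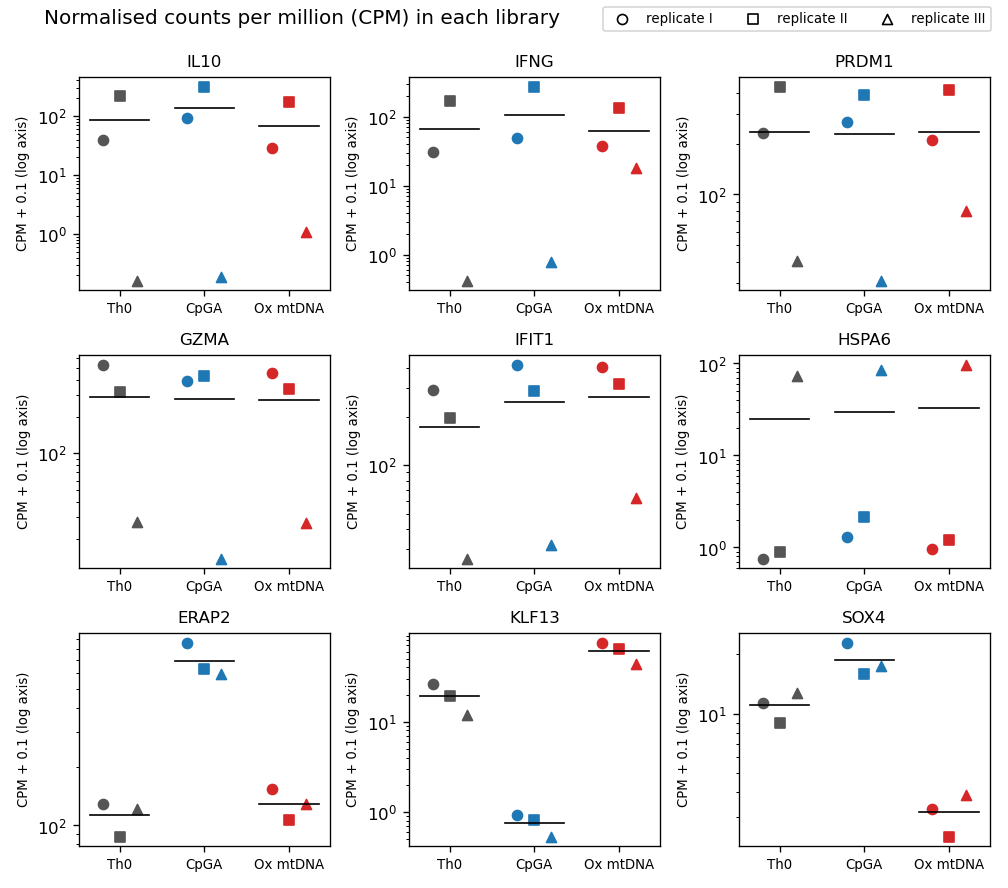
Normalised read counts (CPM) plus 0.1, on a log axis, for 9 genes in each of the 9 libraries, with the mean of each condition as a bar and the replicate number as the shape. IL10, IFNG, PRDM1, GZMA, IFIT1 and HSPA6 separated replicate III from replicates I and II within every condition, while KLF13 and SOX4 separated all 3 condition names and ERAP2 set CpGA-pDC apart.

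ERAP2, which encodes an endoplasmic reticulum aminopeptidase that trims peptides for antigen presentation (ENSG00000164308.16, chromosome 5, 96875939 to 96919716), had the smallest adjusted p of the named rises in the libraries labelled CpGA-pDC against Th0. It stood at 692 ± 143 CPM (SD, n = 3) against 113 ± 21.9 CPM (SD, n = 3), a log2 fold change of 2.62 (SE 0.24, adjusted p = 0.0044). SLC12A7, a potassium and chloride cotransporter gene (chromosome 5, 1050376 to 1112035), rose from 4.07 to 25 CPM (adjusted p = 0.0288), and the ribosomal protein pseudogene RPS28P7 from 13.6 to 78.1 CPM (adjusted p = 0.0229). KLF13, a zinc finger transcription factor gene (chromosome 15, 31326855 to 31435665), fell from 19 ± 7.23 to 0.657 ± 0.204 CPM (adjusted p = 0.00353). MDGA1 (chromosome 6, 37630679 to 37699306) fell from 25.7 to 0.0838 CPM (adjusted p = 0.00459), MTRNR2L8 from 16.3 to 0.194 CPM (0.0125) and the splicing factor gene U2AF1 from 10.2 to 0.211 CPM (0.0323). KLF13, RPS28P7, MTRNR2L8 and U2AF1 can share reads with near-identical copies or alternate loci, so their values are uncertain. For ERAP2, as for every gene called between condition names, culture effects cannot be told apart from different T cell donors behind the names. That possibility is taken up under Other observations. The calls of ERAP2, KLF13 and MDGA1 were kept without any 1 of the 6 libraries, and those of SLC12A7 and U2AF1 were lost without each of the 6. The call of RPS28P7 was kept only without Th0 replicate III, and that of MTRNR2L8 was lost without CpGA-pDC replicate II.

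In this comparison 61 genes changed, 32 higher and 29 lower in CpGA-pDC, and without any 1 of the 6 libraries the count was between 19 and 25. With the replicate number as a block 483 changed, 245 higher and 238 lower, and all 61 were among them with the same sign. Of the 61, 36 (59%) fell in 3 classes that made up 2.72% of the genes tested. They were 32 identifiers without a match in GENCODE 29, 3 antigen receptor segments and 1 identifier in the MHC region. Counts of MHC and receptor features can depend on a person's alleles or receptor repertoire. Those of unmatched identifiers could do so if they lie on alternate loci, which is not known. With the block the 3 classes held 80 of the 483 (16.6%). Without these 3 classes, an alternative chosen after seeing the data, 9 genes changed, and 394 with the block.

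The 13 genes encoded by mitochondrial DNA were the only list to pass between CpGA-pDC and Th0 without the block. They were higher in CpGA-pDC, with a median log2 fold change of 0.19 (camera adjusted p = 0.00125, and 0.981 with an estimated correlation). As single genes 0 of the 13 passed with edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and with the block 3 rose adjusted over the list alone. MT-ND4L, a subunit of respiratory complex I (chromosome M, 10470 to 10766), stood at 1480 ± 114 against 1160 ± 71.4 CPM (log2 fold change 0.35, SE 0.15, adjusted p = 1). With the block, 4 further lists passed, all higher in CpGA-pDC: type I interferon response (adjusted p = 0.000145), heat shock (0.017), regulatory T cell (0.0241) and cholesterol synthesis (0.0425). Each had an adjusted p = 0.935 with the block and an estimated correlation. Of 40 interferon-response genes, 2 rose and 1 fell with the block, and 11 rose and 1 fell adjusted over the list alone. SP110, an interferon-induced nuclear body gene, rose from 78.5 to 124 CPM (adjusted p = 0.00165 with the block; log2 fold change 0.66 without it, and 0.36 without CpGA-pDC replicate I). IRF7, an interferon regulator, fell from 5.08 to 0.149 CPM (adjusted p = 0.0121 with the block), a value that is uncertain for the same reason as KLF13. The CpGA-pDC libraries held only 0.369, 0.0786 and 0 CPM of IRF7. Its log2 fold change without the block moved furthest, to -6.67, without CpGA-pDC replicate I. Of 16 regulatory T cell genes, 3 rose with the block and 7 adjusted over the list alone. These included IKZF2, which encodes the transcription factor Helios, from 19.9 ± 1.82 to 41.7 ± 4.25 CPM (adjusted p = 0.0302 with the block), and TNFRSF18 from 27.9 to 49.9 CPM (adjusted p = 0.035 with the block). SQLE was the 1 cholesterol synthesis gene of 19 that rose with the block, and 3 rose adjusted over the list alone. The log2 fold change of SQLE without the block was 0.68, and 0 without CpGA-pDC replicate III. Of 9 heat shock genes, 0 passed with or without the block, with 0 under an unadjusted p of 0.05 and 0 calls by DESeq2 or limma-voom without it. The cytokine gene IL32 fell with the block, from 1010 to 578 CPM (adjusted p = 0.00101), as did the granzyme gene GZMH, from 12.6 to 2.81 CPM (adjusted p = 0.00108). Of 16 cytotoxic genes 3 fell and 1 rose with the block, or 4 fell and 2 rose adjusted over the list alone, and the list did not pass (adjusted p = 0.404, and 0.183 with the block).

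None of the 13 tested key genes passed between CpGA-pDC and Th0 by edgeR with or without the block, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. IL10 averaged 135 ± 159 CPM in CpGA-pDC and 84.2 ± 114 CPM in Th0 (SD, n = 3 each), a difference smaller than the spread within each group (adjusted p = 1, and 0.124 with the block). Its log2 fold change of 0.68 moved furthest, to 2.8, without Th0 replicate II. The key genes were chosen with knowledge of the study, so their count is not independent evidence. FOXP3, the regulatory T cell factor, averaged 73.7 ± 41 against 50.9 ± 9.78 CPM (adjusted p = 1, and 0.304 with the block), with a log2 fold change of 0.53 that was 0 without CpGA-pDC replicate III. IL4, PDCD1 and SUCNR1, the succinate receptor gene, were too low to test, with at most 23, 2 and 4 counts in any library.

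Between the libraries labelled Ox mtDNA-pDC and Th0, the 3 genes that met the naming rule for a fall, which leaves out HLA, unmatched and receptor segment features, were nuclear copies of mitochondrial sequence. MTATP6P1 (chromosome 1, 633696 to 634376) fell from 551 ± 72.2 to 1.75 ± 0.298 CPM (SD, n = 3 each; log2 fold change -8.29, SE 0.25, adjusted p = 4.3e-06). MTND2P28 (chromosome 1, 629640 to 630683) fell from 206 ± 22 to 2.76 ± 0.964 CPM (adjusted p = 5.91e-05), and MTRNR2L8 (chromosome 11, 10507887 to 10509189) from 16.3 to 0.307 CPM (adjusted p = 0.0134). All 3 resemble mitochondrial DNA closely enough to share its reads, so their values are uncertain. SEMA4A, a semaphorin gene (chromosome 1, 156147366 to 156177752), was the only gene that met the naming rule for a rise, from 2.29 ± 0.229 to 10.1 ± 2.38 CPM (log2 fold change 2.14, SE 0.32, adjusted p = 0.0374), and lost its call without each of the 6 libraries. The pseudogenes MTATP6P1 and MTND2P28 kept theirs in all 6 such fits, and MTRNR2L8 lost it without Th0 replicate I or any 1 of the Ox mtDNA-pDC libraries.

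In this comparison 66 genes changed, 28 higher and 38 lower in Ox mtDNA-pDC, and without any 1 of the 6 libraries the count was between 24 and 30. With the block 923 changed, 437 higher and 486 lower, and all 66 were among them with the same sign. Of the 66, 38 (57.6%) were in the MHC, unmatched and receptor segment classes, against 98 of the 923 (10.6%) with the block. The 38 were 27 unmatched identifiers, 7 in the MHC region and 4 receptor segments. Without those classes 12 genes changed, or 832 with the block.

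Cholesterol synthesis and type I interferon response were higher in Ox mtDNA-pDC than in Th0 as lists. The 19 cholesterol synthesis genes had a median log2 fold change of 0.45 (camera adjusted p = 0.000105, and 0.981 with an estimated correlation; 3.51e-07 with the block). The 40 interferon-response genes had a median of 0.37 (adjusted p = 0.0029, and 0.981 with an estimated correlation; 1.04e-09 with the block). As single genes 0 of either list passed with edgeR without the block, DESeq2 or limma-voom, and 2 and 1 had an unadjusted p under 0.05. With the block, 8 cholesterol synthesis genes rose, and 14 adjusted over the list alone. They included HMGCS1, a cholesterol synthesis enzyme gene, from 109 to 202 CPM (adjusted p = 0.024 with the block), whose log2 fold change without the block was 0.89, and 0.38 without Ox mtDNA-pDC replicate III. Of the interferon-response genes, 12 rose and 1 fell with the block, and 30 rose and 2 fell adjusted over the list alone. SP110 rose from 78.5 to 115 CPM (adjusted p = 0.0025 with the block) and IFIT2 from 35.5 to 70.6 CPM (0.0155 with the block; log2 fold change 0.99 without it, and 1.69 without Th0 replicate I), while LY6E fell from 50.8 ± 44.3 to 0.735 ± 0.495 CPM (0.0169 with the block), an uncertain value for the same reason as KLF13. In replicate III LY6E did not fall, at 0.318 CPM in Th0 and 0.357 CPM in Ox mtDNA-pDC. The cytotoxic list was higher with the block alone (adjusted p = 0.00406, and 0.935 with an estimated correlation), with 3 of 16 members higher, and 8 adjusted over the list alone. GZMH rose from 12.6 to 28.3 CPM (adjusted p = 0.00486 with the block; log2 fold change 1.17 without it, and 0.64 without Ox mtDNA-pDC replicate II) and the receptor gene KLRD1 from 1.7 to 4.87 CPM (0.0123 with the block). EOMES, a transcription factor gene of cytotoxic and memory T cells, rose from 0.999 to 8.71 CPM (0.00163 with the block). The log2 fold change of EOMES without the block moved furthest, to 2.44, without Ox mtDNA-pDC replicate II. The cell cycle list was lower with the block alone (adjusted p = 0.0485, and 0.935 with an estimated correlation; 1 of 35 genes fell).

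IL3, a haematopoietic growth factor gene, was the 1 key gene of 13 that passed between Ox mtDNA-pDC and Th0, and only with the block. It fell from 5.41 ± 8.43 to 0.579 ± 0.758 CPM (log2 fold change -3.05, adjusted p = 0.00472 with the block; 1 without it). The level in Th0 rested on replicate II, at 15.1 CPM, and without that library the log2 fold change went from -3.2 to 0.12. IL10 averaged 67.7 ± 92.4 CPM in Ox mtDNA-pDC and 84.2 ± 114 CPM in Th0 (adjusted p = 1, and 0.62 with the block), with a log2 fold change of -0.31 that moved furthest, to -2.49, without Ox mtDNA-pDC replicate II. Among the mtDNA-encoded genes MT-ND2 rose with the block, from 2860 to 3470 CPM (adjusted p = 0.0349), and the list did not pass (adjusted p = 0.785, and 0.649 with the block). MT-ND2 can share reads with the nuclear copy MTND2P28, which fell in the same comparison, so the rise of MT-ND2 is uncertain.

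The aminopeptidase gene ERAP2 was at 130 ± 24.2 CPM in the libraries labelled Ox mtDNA-pDC and 692 ± 143 CPM in those labelled CpGA-pDC (SD, n = 3 each; log2 fold change -2.42, SE 0.24, adjusted p = 0.00453). The actin-capping gene CAPG (chromosome 2, 85394748 to 85418432) fell from 75.5 ± 5.15 to 27.3 ± 3.73 CPM (adjusted p = 0.00628), and the transcription factor gene SOX4 (chromosome 6, 21592768 to 21598619) from 18.6 ± 3.66 to 3.08 ± 0.758 CPM (adjusted p = 0.00646). KLF13 rose from 0.657 ± 0.204 to 60.8 ± 16 CPM (log2 fold change 6.51, SE 0.44, adjusted p = 0.00054). GZMH (chromosome 14, 24606480 to 24609699) rose from 2.81 ± 0.777 to 28.3 ± 15.6 CPM (adjusted p = 0.0482). MTATP6P1 fell from 616 to 1.75 CPM (adjusted p = 3.85e-06) and MTND2P28 from 216 to 2.76 CPM (6.66e-05). RPS28 rose from 4.75 to 29.5 CPM (0.0163) and U2AF1 from 0.211 to 11.3 CPM (0.0251). These 4 and KLF13 are uncertain for the reason given above. The calls of ERAP2, CAPG, SOX4, KLF13 and both mitochondrial pseudogenes were kept without any 1 of the 6 libraries, and that of GZMH was lost without each of them. RPS28 lost its call without CpGA-pDC replicate I or II, and U2AF1 without CpGA-pDC replicate III or any 1 of the Ox mtDNA-pDC libraries.

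In this comparison 79 genes changed, 41 higher and 38 lower in Ox mtDNA-pDC, and without any 1 of the 6 libraries the count was between 29 and 39. With the block 924 changed, 410 higher and 514 lower, and all 79 were among them with the same sign. Of the 79, 52 (65.8%) were in the MHC, unmatched and receptor segment classes, against 117 of the 924 (12.7%) with the block. The 52 were 40 unmatched identifiers, 6 in the MHC region and 6 receptor segments. Without those classes 14 genes changed, or 803 with the block.

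Cytotoxic genes were higher in Ox mtDNA-pDC than in CpGA-pDC as a list of 16, with a median log2 fold change of 0.58 (camera adjusted p = 0.00692, and 0.981 with an estimated correlation; 0.000522 with the block). Of these, 1 rose, or 2 adjusted over the list alone, and 6 rose with the block, or 8 rose and 1 fell adjusted over the list alone. With the block KLRD1 rose from 1.08 to 4.87 CPM (adjusted p = 0.00325) and GZMM from 9.93 to 20.9 CPM (0.00381). The 19 cholesterol synthesis genes were higher, with a median of 0.24 (adjusted p = 0.0413, and 0.981 with an estimated correlation; 0.00119 with the block, and 0.0639 with library totals as the only scaling). With the block 3 rose, or 6 adjusted over the list alone, HMGCS1 among them (adjusted p = 0.0318 with the block; log2 fold change 0.82 without it, and 0.31 without Ox mtDNA-pDC replicate III). The 35 cell cycle genes were lower, with a median of -0.13 (adjusted p = 0.0413, and 0.981 with an estimated correlation; 0.000156 with the block), and 4 fell with the block, or 7 adjusted over the list alone. CDC20, an activator of mitotic exit, fell from 99.4 to 77.6 CPM (adjusted p = 0.0486 with the block; log2 fold change -0.36 without it, and -0.56 without Ox mtDNA-pDC replicate II). With the block alone the interferon-response list was higher (adjusted p = 0.0112) and the regulatory T cell list lower (adjusted p = 0.0277), each with an adjusted p = 0.935 with an estimated correlation. Of the 40 interferon-response genes 0 passed with the block, and 0 adjusted over the list alone. Of the regulatory T cell genes 8 of 16 fell with the block, and adjusted over the list alone 8 fell and 1 rose. IKZF2 fell from 41.7 ± 4.25 to 11.4 ± 4.84 CPM (log2 fold change -1.87, SE 0.32, adjusted p = 0.0519, and 0.0018 with the block).

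Of the 13 key genes, 3 fell in Ox mtDNA-pDC against CpGA-pDC with the block and 0 without it, where 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. IL10 fell from 135 ± 159 to 67.7 ± 92.4 CPM (log2 fold change -1.16, adjusted p = 0.0381 with the block; 1 without it). In replicate III it went the other way, from 0.0863 to 1 CPM, and its log2 fold change without the block, -0.99, was -3.17 without Ox mtDNA-pDC replicate II. IL3 fell from 4.36 to 0.579 CPM (0.00837 with the block; log2 fold change -2.89 without it, and 0.51 without CpGA-pDC replicate II), as did CD40LG, the B cell co-stimulation ligand gene, from 126 to 84.5 CPM (0.0309 with the block; log2 fold change -0.58 without it, and -0.07 without CpGA-pDC replicate II). MT-ND4 (chromosome M, 10760 to 12137) fell from 13300 ± 1430 to 9920 ± 372 CPM (adjusted p = 0.0104 with the block; 1 without it), and the mtDNA-encoded list did not pass (adjusted p = 0.079, and 0.127 with the block). Of its 13 genes 3 fell with the block, or 6 adjusted over the list alone; without the block 0 passed with edgeR or limma-voom, 1 with DESeq2, and 2 had an unadjusted p under 0.05. The 8 Complex II genes, which encode succinate dehydrogenase and its assembly factors, did not pass in any of the 3 comparisons, with a lowest adjusted p of 0.882 for the list, or 0.905 with the block. SDHA stood at 137 ± 20.8 CPM in Th0, 147 ± 23.3 CPM in CpGA-pDC and 144 ± 32 CPM in Ox mtDNA-pDC.

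Mitochondrially encoded genes held 6.63 ± 0.73% of the counts in CpGA-pDC, 5.8 ± 0.48% in Th0 and 5.78 ± 0.38% in Ox mtDNA-pDC (SD, n = 3 each). CpGA-pDC was higher than Th0 in 3 of 3 pairs of libraries with the same number, by 0.83 percentage points on average (two-sided exact permutation p = 0.2). It was also higher than Ox mtDNA-pDC in 3 of 3 such pairs, with Ox mtDNA-pDC minus CpGA-pDC at -0.845 points (exact permutation p = 0.2). Ox mtDNA-pDC and Th0 differed by -0.0142 points (exact permutation p = 1). Without CpGA-pDC replicate III, CpGA-pDC minus Th0 was 0.481 points and Ox mtDNA-pDC minus CpGA-pDC -0.495 points. The p-values ignore the pairs, and a comparison of 3 with 3 libraries cannot go below 0.1. Ribosomal RNA (rRNA) of the mitochondria held 1.207%, 0.792% and 2.15% of the counts in the Th0 libraries I, II and III. It held 1.501%, 0.902% and 2.341% in CpGA-pDC and 1.516%, 1.093% and 2.039% in Ox mtDNA-pDC. This rRNA was thus also higher in CpGA-pDC than in Th0 for each number. Against Ox mtDNA-pDC it did not follow the share of the encoded genes. In numbers I and II it was higher in Ox mtDNA-pDC than in CpGA-pDC, and in number III it was lower.

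Among all 3 groups 128 genes changed, and 1337 with the block. The changes of both co-cultures against Th0 shared 18 genes in the same direction, 8 higher and 10 lower, and 0 in opposite directions. The overlap with DESeq2 was 58 genes. With the block 198 were shared in the same direction, 89 higher and 109 lower, and 13 in opposite directions. Independent lists of these sizes would share 0.0594 higher and 0.0731 lower genes, or 7.1 and 7.67 with the block. Simulated unchanged groups against shared controls gave at most 0 shared genes, or 2 with the block. The simulation held no difference particular to the Th0 libraries. Such a difference would move both comparisons the same way, so an effect of the co-cultures cannot be told apart from it. The fold changes correlated across genes, which are not independent replicates, at r = 0.398, against 0.486 in the simulation, and their covariance was 0.171 against 0.0345. The 3 Th0 libraries that both comparisons share are too few to split.

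T cell identity and the sort were described with marker lists. The 12 CD4 T cell identity genes summed to between 3360 and 4800 CPM in the 9 libraries. B cell markers summed to at most 46 CPM, CD8 and NK cell markers to at most 11.5 CPM, and red cell and platelet markers to at most 1.81 CPM. Plasmacytoid dendritic cell markers summed to between 56 and 139 CPM, with 66.1, 92.3 and 96.5 CPM in the Th0 libraries, which were cultured without pDCs. Monocyte and myeloid markers summed to between 57.9 and 282 CPM, of which ITGAX alone held between 37.9 and 265 CPM. None of these lists, nor the lists for Th1, Th2, Th17, T follicular helper, Tr1 and IL10 regulators, inhibitory receptors, secreted cytokines, chemokine and homing receptors, naive and central memory, early T cell receptor response, TCA cycle, succinate handling, nuclear-encoded respiratory chain, reactive oxygen and antioxidant, glycolysis, fatty acid oxidation, integrated stress and unfolded protein response, and key genes passed between the condition names. With Complex II these made 25 lists, whose lowest adjusted p was 0.322, or 0.108 with the block. Of all 96 list tests 6 passed, 12 had an unadjusted p under 0.05 and 14 passed with the block, while 0 passed with fry or with an estimated correlation.

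**Figure D3:**
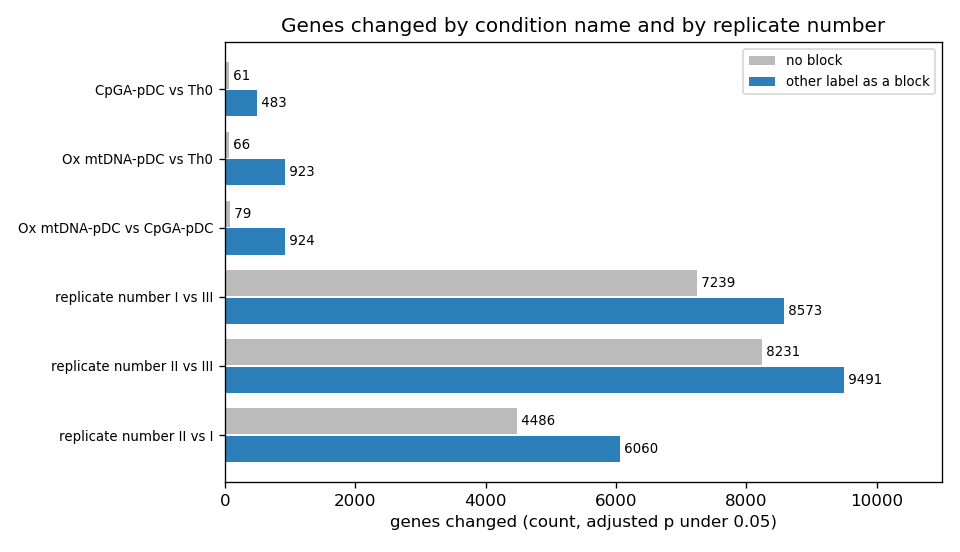
Genes changed (count, edgeR adjusted p under 0.05) in comparisons of condition names and of replicate numbers, without a block in grey and with the other label as a block in blue. The condition names gave 61, 66 and 79 genes without a block, and the replicate numbers 7239, 8231 and 4486.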

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

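The settings without allele-dependent features, those with a replicate number left out, the block with a minimum log2 fold change or with an estimated correlation, and all settings of the comparisons between replicate numbers were chosen after seeing the data. Allele-dependent features here means the MHC, unmatched and receptor segment classes, although this dependence is not known for the unmatched identifiers. For each count of changed genes, values are given in the order CpGA-pDC against Th0, Ox mtDNA-pDC against Th0, Ox mtDNA-pDC against CpGA-pDC and all 3 groups, and the counts of 61, 66, 79 and 128 stayed within 1.5 times under the other scalings, both other filters and limma-voom. They were 148, 171, 186 and 296 with DESeq2, and 483, 923, 924 and 1337 with the replicate block. With an adjusted p under 0.01 they were 18, 24, 26 and 37, because the threshold is stricter. With only the 2 groups compared they were 26 and 35 for the comparisons with Th0, where fewer libraries were fitted. Without allele-dependent features they were 9, 12, 14 and 18, and 394, 832, 803 and 1206 with the block as well; without the block those features held 36, 38, 52 and 79 of the calls, which accounts for only part of the fall. With the block and number I left out they were 103, 208, 265 and 314, with number II left out 119, 181, 198 and 275, and with number III left out 875, 1631, 1601 and 2235. With the block and a log2 fold change of at least 1 the first 3 were 238, 395 and 458. Without any 1 library they ranged from 19 to 25, 24 to 30, 29 to 39 and 48 to 83, so every library moved them. The counts between numbers ranged from 7237 to 8389 (I against III), 8360 to 9473 (II against III), 4208 to 5056 (II against I) and 10257 to 11228 (all 3) without any 1 library, and moved by more than 1.5 times only with a log2 fold change of at least 1, to 2944, 3214 and 962 for the first 3.

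The overlap of 18 genes was 58 with DESeq2 and 198 with the block. Of 96 list tests 6 passed, 14 with the block, and 0 with an estimated correlation, with fry, or with the block and an estimated correlation. Where no reason is given for a changed value the cause was not tested. Of the fold changes of named genes under other settings, 537 kept their sign and side of the threshold, 36 passed where they had not, 14 no longer passed and 6, none of them past the threshold, changed sign or went to 0. These counts take, of the fits without 1 library, only the one with the most different fold change for each gene, so they understate lost calls; the calls lost in each such fit stand beside the genes in the report. The differences in mitochondrial share moved by less than the spread between replicates, but ranged from 0.481 to 1.21 (CpGA-pDC minus Th0), -0.226 to 0.249 (Ox mtDNA-pDC minus Th0) and -1.23 to -0.495 points (Ox mtDNA-pDC minus CpGA-pDC) without any 1 library. The block changed calls of genes, lists and the overlap, as given beside each result, and ended none of the 61, 66 and 79 calls. Depth limits mainly genes with few counts, such as IL4, PDCD1 and SUCNR1, which were not tested.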

Other observations

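The comparisons between replicate numbers, their settings, and the tests on allele-dependent features and on a donor per condition were chosen after the data were seen; the tests on donor-variable genes, on depth and on other splits were fixed before their results were seen. IL10 averaged 233 ± 70.7 CPM in number II and 0.383 ± 0.534 CPM in number III (SD, n = 3 each; log2 fold change 9.18, and 11.69 without Ox mtDNA-pDC replicate III; edgeR adjusted p = 6.93e-07). IFNG averaged 190 ± 71.4 against 6.22 ± 9.9 CPM (adjusted p = 0.00034; log2 fold change 5.02, and 8.69 without Ox mtDNA-pDC replicate III), FASLG, the Fas ligand gene, 59.8 against 2.08 CPM, and PRDM1, which encodes the transcription factor Blimp-1, 414 against 50.4 CPM. The secreted cytokine list did not pass, with 8 genes higher and 8 lower (camera adjusted p = 0.794), nor did the early T cell receptor response list, with 1 higher and 12 lower (0.0653). BCL6, the antagonist of PRDM1 in follicular helper cells, averaged 13.8 against 77.3 CPM (adjusted p = 6.9e-07). Of 16 cytotoxic genes 15 rose and 0 fell (camera adjusted p = 4.16e-05, and 0.438 with an estimated correlation), and of 40 interferon-response genes 33 rose and 2 fell (2.78e-07, and 0.62 with an estimated correlation). Of 23 glycolysis genes 15 fell and 2 rose, ENO2 from 368 to 49.3 CPM (list adjusted p = 0.000757, and 0.62 with an estimated correlation). In number I against III, 16 of 16 cytotoxic genes and 37 of 40 interferon-response genes rose, with GZMA at 458 against 22.6 CPM and IFIT1 at 373 against 39.9 CPM (camera adjusted p = 3.83e-06 and 2.42e-11, and 0.438 and 0.579 with an estimated correlation). Of 9 heat shock genes 8 fell, HSPA6 from 84.9 to 0.906 CPM, and of 23 glycolysis genes 18 fell, PGK1 from 1900 to 757 CPM (9.59e-05 and 1.5e-05, and 0.575 for each with an estimated correlation). The chemokine receptor gene CXCR4 fell from 339 to 29.9 CPM, and the homing receptor gene GPR15 rose from 4.66 to 274 CPM. Of 12 CD4 T cell identity genes 11 rose and 1 fell (camera adjusted p = 0.00119, and 0.575 with an estimated correlation). In number II against III 10 of these rose and 1 fell (0.0383, and 0.62 with an estimated correlation). Mitochondrial rRNA held between 2.039% and 2.341% of the counts in the libraries numbered III and between 1.207% and 1.516% in number I, and myeloid markers summed to between 171 and 282 CPM in number I and between 57.9 and 103 CPM in number III. Most of these marker sums came from ITGAX, at 162 to 265 CPM in number I and 37.9 to 89.7 CPM in number III. Of the 6 tested myeloid markers 2 rose and 1 fell in number I against III, and the list did not pass (camera adjusted p = 0.427). CD33 went the other way, at 0.729 to 1.87 CPM in number I and 5.72 to 9.67 CPM in number III.

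Number II was also higher than number I in the cell cycle, TCA cycle, nuclear-encoded respiratory chain, heat shock (camera adjusted p = 0.000806) and integrated stress (0.000682) lists, of which none passed with an estimated correlation (adjusted p from 0.485 to 0.575). The secreted cytokine (0.109), mtDNA-encoded (0.216) and Complex II lists (0.0744, with 4 of 8 genes higher) did not pass. Mitochondrial rRNA held between 0.792% and 1.093% of the counts in number II, below number I, and the nuclear RNA MALAT1 between 0.161% and 0.235% in number II and between 0.406% and 0.468% in number I. IL10 averaged 233 against 53.8 CPM (log2 fold change 2.23, SE 0.23, adjusted p = 0.000163), IFNG 190 against 38.8 CPM (adjusted p = 0.0137) and IL3 9.61 against 0.682 CPM (0.000134); with DESeq2 neither IL10 nor IFNG passed, and without the group block IFNG did not. SDHA, the catalytic subunit gene of succinate dehydrogenase, averaged 171 ± 11.1 against 123 ± 7.03 CPM (0.000419), and GPD2, a mitochondrial glycerol-3-phosphate dehydrogenase gene, 68.4 against 47.6 CPM (0.00305). Of 35 cell cycle genes 30 rose and 0 fell (camera adjusted p = 3.79e-11, and 0.575 with an estimated correlation), MCM4 from 251 to 481 CPM. Of 22 TCA cycle genes 17 rose and 1 fell (2.18e-05, and 0.485 with an estimated correlation), of 69 nuclear-encoded respiratory chain genes 33 rose and 1 fell (2.78e-07, and 0.575 with an estimated correlation), and of 16 succinate handling genes 10 rose and 0 fell (0.000747, and 0.438 with an estimated correlation). Of 40 interferon-response genes 15 fell and 0 rose, TRIM22 from 782 to 341 CPM (0.00759, and 0.771 with an estimated correlation). Of 16 naive and central memory genes 11 fell and 0 rose (0.000106, and 0.438 with an estimated correlation), CCR7 from 383 to 158 CPM. Cholesterol synthesis (0.000806) and reactive oxygen genes (0.00016) were higher as lists and CD4 identity genes lower (0.00523), with adjusted p = 0.575, 0.438 and 0.575 with an estimated correlation. Over the 3 comparisons of numbers 29 of 96 list tests passed, and 0 did with an estimated correlation, against 56 with fry.

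Expression followed the replicate number more than the condition name, with 11114 genes changed among the 3 numbers, and a difference in depth is argued against, since 10707 genes changed after all libraries were thinned to equal totals. A shared T cell donor behind each number remains open. It was tested on 13 genes known to vary between people, the tested members of a list of 24. CHURC1 and PILRB were left out because their values had been seen, and the rest was fixed before. The 13 had a median variance share of 45.9% by number and 40.6% by condition name. This met by a small margin the condition set for it, a larger median share by number. Over all genes tested the median shares were 76.4% and 9.3%, so most lists would meet that condition and it cannot decide. The share by condition name lay at the 99.96 percentile of 10000 expression-matched random lists. As set in advance, the condition of a larger share by number would alone have counted as in favour of a donor behind each number. The features described in the next paragraph were added as a further criterion after the shares had been seen, and with them the explanation is left open. A candidate explanation that these tables cannot exclude is that condition names and replicate numbers were exchanged in the labels, under which the names would mark donors; 6 of the 13 genes followed the name more than the number, and the larger median share by name that had been set as its condition was not found. A single donor per condition with an unrecorded batch behind the numbers cannot be told apart from it, since donor and name would coincide in the 1337 genes changed among the names with the block, and no biological explanation for the numbers was tested.

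Genes called between condition names concentrated in 3 classes of features, some of whose counts can depend on alleles or receptor repertoire. Of the 128 genes changed among the 3 names, 61.7% were in the MHC region, unmatched in GENCODE 29 or receptor segments, against 2.72% of the genes tested. These 79 calls were 63 unmatched identifiers, 9 in the MHC region and 7 receptor segments. Most of the concentration thus rested on unmatched identifiers, whose dependence on alleles is not known. With the replicate block the share of the 3 classes was 16.6%, 10.6% and 12.7% in the 3 comparisons of names. The last 2 of these were under the 5 times the tested share that the test asked for. With the group as a block the share was 1.56% among the numbers, 173 of 11114 calls. Only 411 tested genes were in these classes, so among 11114 calls the share could not have risen far above 2.72%. The 1.56% therefore cannot be set against the 61.7% as a contrast. The concentration among the names may mean that different T cell donors stood behind the condition names. That hypothesis was found and tested on the same data, and a biological effect of the culture conditions on these features was not tested.

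Other splits of the libraries were counted for each comparison. For 3 against 3 libraries the 10 splits are too few for a share under 0.05; the real split was the 1 with the most genes in each comparison. Between condition names it gave 61, 66 and 79 genes, against at most 0 in the other splits of each, and with the block 483, 923 and 924 against at most 0, 0 and 1 in the other splits that part all 3 pairs. Between numbers it gave 7239 (I against III), 8231 (II against III) and 4486 (II against I), against at most 0, 0 and 1. Of the 280 splits of all 9 libraries into 3 groups, 100 were counted. The splits by name and by number were included on purpose, and the rest were drawn at random. For the 128 genes among the 3 names, 6 of the 100 gave as many, so chance is not excluded by that count. The highest, with 9695 genes, was the split by number itself. Among the 11 of the 100 that put 1 library of each number in each group, the highest other gave 19. For the 9695 genes among the 3 numbers without a block, 1 of 100 splits, the real one, gave as many, the highest other gave 4871, and chance is excluded at that level.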
